A study of Homo sapiens with 4 samples.

How the data were processed

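RNA from 4 cultures was analysed, a control and a CC-292 culture of each of 2 human MCL cell lines, REC-1 and Z138. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was prepared from 150 ng by the Affymetrix protocol. The deposited values are log2 probe-set signals, and per the submitters' processing notes RMA and Affymetrix Expression Console 1.1 were used. Their settings, and which arrays were processed together, are not given in the sources used here. RMA commonly includes quantile normalization, and the 4 columns had nearly equal quartiles, so a shift of most genes in one direction would not show. The log2 scale was inferred from the range of the deposited values, 2.18 to 14.26.

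The table held 49386 probe sets, of which 93 were array controls. In the probe table used, 45259 had 1 gene symbol, 1327 had several and 2800 had none. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCh38.p14, where 45178 probe sets matched and no symbol changed. Probe sets with several symbols or none were left out of gene results. A gene was represented by the probe set with the highest mean over the 4 arrays, which gave 18239 genes. It was kept if the highest of its 4 values reached the median of all values (log2 4.63), which left 10823 genes. A gene kept through 1 line could thus lie below this minimum on both arrays of the other. A stricter minimum at the 70th percentile (log2 6.61) left 7707. No genome build was named, and no coordinates are given. Depth has no counterpart on arrays, and their number, 1 per group, limits the precision.

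Each array was assigned to its group by its GEO title, and no column was left without a sample. Comparisons were the CC-292 minus control difference in each line, the difference of those differences, and REC-1 control minus Z138 control. With 1 array per group these have no test, and genes at least 2-fold different were counted. The average effect over both lines was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, cell line as a block), with Benjamini-Hochberg adjustment. Nothing in the labels says how the cultures of the lines were grown relative to each other. The p-values and SEs of this fit are moderated. eBayes draws the spread of each gene between the 2 lines (1 degree of freedom) towards a prior estimated from all genes (4.5 degrees of freedom). The spread between lines includes any real difference in their response. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for the rest.

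For 24 gene lists, the median difference was set against 10000 random lists of the same size drawn from genes in the same 20 bins of mean expression. A list stood apart below the 2.5th or above the 97.5th percentile. Some lists share members, such as CD83 (B-cell receptor response and NF-kB targets), CCL3 (B-cell receptor response and chemokines) and CD40 (both NF-kB lists). The 24 lists, the comparisons and their tests, the rule for named genes and all alternatives but 1 were fixed before the data were examined. A test of MAP3K14, a check with an artificial brightness trend and 9 gene families were chosen after.

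The rule for named genes took, per line and for the controls, the 10 highest and 10 lowest genes. It also took the 5 highest and 5 lowest of the difference between lines, and the 5 genes with the largest smaller difference in each direction for both lines. From each list it took up to 4 members with a difference of at least 1, of which the text gives a part. Finally, 15 genes were fixed by name, of which 12 are reported. BIRC3, TRAF2 and CCL4 had no kept probe set with a single symbol and are not analysed here.

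The procedures were tested on simulated data. For the average effect over both lines, with 10823 genes, limma recovered 23 of 100 genes changed 2-fold and 98 of 100 changed 4-fold, with 6 false calls. For the REC-1 difference, with 10823 genes, 34 of 40 lists of 25 genes shifted by 0.3 and 2 of 40 unshifted lists stood apart. These were randomly picked genes with independent noise, so they do not show how often lists of genes that vary together stand apart. In the same simulation, 187 of 200 genes changed by 1.5 on the log2 scale were counted as 2-fold, with 38 unchanged genes. Alternatives were no brightness filter, the 70th percentile, centring of arrays on their medians, quantile normalization, cyclic loess, the mean of all probe sets, the probe set with the median difference, thresholds of 1.5-fold and 3-fold, limma with an intensity trend, and limma without the block. The mean and the median difference took all probe sets of a gene with 1 symbol, also those below the brightness minimum. The SDs and means given for single genes took only probe sets that reached it. After the data were seen, agreement of a second probe set was added as an alternative.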

Results

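Gene expression was measured in 2 human mantle cell lymphoma (MCL) cell lines, REC-1 and Z138. MCL is a B-cell malignancy whose hallmark is a translocation that places the cyclin D1 gene CCND1 under immunoglobulin heavy chain control. Each line was profiled once as a control and once after exposure to CC-292, an inhibitor of Bruton tyrosine kinase (BTK), the kinase that carries the B-cell receptor signal towards NF-kB. The 4 arrays thus form 4 groups of 1 array, with no replicates, and the labels give 48 h of exposure. The treatment protocol gives 1 uM CC-292 whereas the titles of the treated arrays give 1 mM, and the title of the Z138 control gives no time. The title of the series relates the activity of CC-292 to NF-kB mutational status. No label used here states that status for either line.

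Differences are log2 values, CC-292 minus control within a line, so that 1 stands for a 2-fold difference. Because each group is 1 array, no p-value is given for a single line. The value of a gene is that of its brightest probe set, and the SD over its probe sets is given as their spread. This SD holds no error between cultures or arrays, which 1 array per group leaves unknown. For several genes the mean over probe sets is given instead of the SD, where it was under 50% of the value. For a gene with 1 probe set the pooled SD between probe sets of a gene applies, 0.31 for the REC-1 difference, 0.25 for the Z138 difference and 0.48 for the difference between controls. A list of genes stood apart when its median lay outside the central 95% of 10000 random lists of like brightness, which describes these arrays and not the conditions. Of 24 lists of independently varying genes, 1.2 would stand apart by chance in each comparison. Genes of 1 list can vary together and some lists share members, so the number for these lists is not known. List members named as examples with less than a 2-fold difference were chosen after their values were seen.

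Median values were 4.64 and 4.64 for REC-1 and 4.63 and 4.63 for Z138, and nonspecific background probes had medians of 3.06 to 3.12. The paired arrays of a line correlated across probe sets with Pearson r = 0.987 in REC-1 and 0.991 in Z138, against 0.922 to 0.926 between lines (probe sets are not independent replicates). The difference between 3' and 5' probe sets of ACTB, a sign of RNA integrity, was 0.77 and 0.53 on the REC-1 control and CC-292 arrays and 1.12 and 1.11 on the Z138 arrays. That of GAPDH lay between -0.32 and -0.24 on all 4 arrays. Hybridization controls differed by a median of -0.07 in REC-1, 0.09 in Z138 and 0.33 between the control arrays, REC-1 minus Z138 (0.17 to 0.53 over 9 probe sets).

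The first comparison asked what differed in REC-1 after CC-292. In REC-1, genes that the B-cell receptor and NF-kB switch on were lower as sets on the CC-292 array. Lower members were the chemokine gene CCL3, the cytokine gene LTA, and the NF-kB genes RELB and TNFAIP3, while some members were higher. Genes of DNA replication and mitosis, MYC target genes and genes of the ATF4 stress response were lower as sets, with ATF3 3.77-fold lower. Interferon-response genes such as IFIT3, and quiescence genes such as TXNIP, an inhibitor of glucose uptake that was 2.23-fold higher, were higher. Components of the B-cell receptor pathway were also higher as a set. Of 10823 genes, 91 were at least 2-fold higher and 82 at least 2-fold lower (1.60% of genes). A gene below the brightness minimum on both REC-1 arrays could be counted if it reached that minimum in Z138.

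BTK itself, the target of CC-292, had a log2 difference of 0.17 (SD 0.10 over 2 probe sets), and CCND1 one of 0.07 on its brightest probe set but -0.26 as the mean of 4. MYC differed by 0.36 on 1 probe set. The lymphocyte transcription factor gene IRF4 was lower at -0.70 (SD 0.20 over 2 probe sets), while IKZF1, IKZF3 and CRBN, genes of the lenalidomide target axis, differed by 0.07, 0.26 and 0.31 (SD 0.17, 0.05 and 0.12 over 3, 2 and 3 probe sets). The kinase gene MAP3K14, which encodes NIK of the alternative NF-kB pathway, was 1.43 higher (4.25 on the control and 5.68 on the CC-292 array). Its second probe set stayed below the brightness minimum on every array, with a highest value of 4.21. NFKB2 differed by 0.33, NFKBIA by -0.32 (SD 0.06 over 3 probe sets) and TRAF3 by -0.07 (SD 0.26 over 3 probe sets).

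Among NF-kB target genes, 19 of 24 measured members were below 0, with a median of -0.36 that lay below all 10000 random lists. Of these, 6 were at least 1.5-fold lower, including LTA at -1.10, RELB at -0.92, TNFAIP3 at -0.75 (SD 0.11 over 2 probe sets) and the costimulatory receptor gene CD40 at -0.71 (SD 0.29 over 2 probe sets). The 5 members above 0 included CCR7 at 0.96, LTB at 0.48 and NFKB2 at 0.33. Of B-cell receptor and MAPK response genes, 16 of 19 were below 0, with a median of -0.37 at the 0.07th percentile. This list held CCL3 at -1.59, RGS1, SPRED2 at -0.90, CD83 at -0.74 and EGR1 at -0.66 (SD 0.36 over 5 probe sets). It also held 3 members above 0, among them MYC at 0.36 and SPRY2 at 0.32. Its median was -0.12 with the mean of all probe sets of a gene and -0.11 with the probe set of median difference, and with both it lay within the range of random lists. The chemokine gene CXCL10 was also lower, at -1.48, although chemokine, homing receptor and adhesion genes as a list (median 0.05) did not stand apart. Alternative NF-kB pathway components (median -0.06, 8 of 12 below 0) did not stand apart either.

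Cell-cycle genes were lower in REC-1 in nearly every case, from CCNE1 at -0.75 to PLK1 at 0.12. All 28 measured genes of G1/S and DNA replication were below 0 (median -0.34), and 29 of 30 genes of G2/M and mitosis were below 0 (median -0.29), both below all random lists. Examples beside the cyclin gene CCNE1 were CCNE2 at -0.57 (SD 0.11 over 2 probe sets), the phosphatase gene CDC25A at -0.63 (SD 0.27 over 3 probe sets) and the ribonucleotide reductase gene RRM2 at -0.39 (SD 0.02 over 2 probe sets). HMMR at -0.55 (mean -0.23 over 4 probe sets) and TPX2 at -0.51 belonged to the mitotic list. So did the proliferation marker gene MKI67, at -0.33 on its brightest probe set but -0.03 as the mean of 6. None of these 58 genes reached a 2-fold difference. MYC target genes had a median of -0.21, with 24 of 26 below 0, among them the RNA polymerase I subunit gene POLR1B at -0.65 (mean -0.25 over 6 probe sets) and NOP2 at -0.42 (SD 0.13 over 3 probe sets).

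The amino-acid and ER stress response driven by ATF4 and CHOP had the lowest list median in REC-1, -0.40, with 26 of 31 members below 0. ATF3 was at -1.91, CHAC1 at -0.96, TRIB3 at -0.93 (SD 0.02 over 2 probe sets), DDIT3, which encodes CHOP, at -0.74 (SD 0.20 over 2 probe sets), and ASNS, the asparagine synthetase gene, at -0.35 (SD 0.10 over 4 probe sets). Plasma-cell differentiation genes were lower in 12 of 16 cases (median -0.30), among them the BCMA gene TNFRSF17 at -0.81, IRF4, and the secretory regulator gene XBP1 at -0.59. That median was -0.15 with the mean of probe sets and -0.10 with the probe set of median difference, inside the random range. Glycolysis and hypoxia genes had a median of -0.22 with 23 of 30 below 0, including ANKRD37 at -1.11, VEGFA at -0.61 (SD 0.35 over 10 probe sets) and GAPDH at -0.28 (mean -0.12 over 4 probe sets).

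Lists that stood higher in REC-1 were led by the type I interferon response, with a median of 0.35 and 20 of 25 members above 0. IFIT3 was 1.44 higher, ISG15 0.89, TRIM22 0.85 (SD 0.14 over 6 probe sets) and OAS1 0.80 (mean 0.36 over 3 probe sets), although IFIT3 and OAS1 were dim. B-cell receptor pathway components had a median of 0.24 with 20 of 22 above 0, including the adaptor gene BANK1 at 0.81 (SD 0.16 over 3 probe sets), VAV1 at 0.51 (SD 0.09 over 2 probe sets) and PIK3R1 at 0.40 (mean 0.12 over 8 probe sets). FOXO and quiescence genes were above 0 in 15 of 20 cases (median 0.21), with TXNIP at 1.16 (SD 0.25 over 5 probe sets), YPEL5 at 0.52 (SD 0.07 over 2 probe sets), CCNG2 at 0.42 (SD 0.15 over 4 probe sets) and the p27 gene CDKN1B at 0.40 (SD 0.19 over 2 probe sets). GABARAPL1 of the same list was lower, at -0.90. B-cell identity genes had a median of 0.15 with 15 of 18 above 0, for example CD52 at 0.56 (SD 0.11 over 2 probe sets) and EBF1 at 0.48 (mean 0.14 over 3 probe sets).

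The 10 highest genes in REC-1 were RGPD4 (1.92, SD 0.80 over 3 probe sets), the monocarboxylate transporter gene SLC16A4 (1.77, SD 0.32 over 4 probe sets), LOXHD1, ANKRD36, the metallothionein gene MT1E, the actin regulator gene MTSS1 (1.64, the same on 2 probe sets), MPEG1, GNB3, H2BC15 and SDHAP4. The 10 lowest were ERICH3 (-2.10), ATF3, SHB, HSD11B2, CCL3, NLRP11, HMGN5, CHRNB2, TCL1B (-1.51) and CXCL10. MT1E on the control array and SHB and HMGN5 on the CC-292 array lay below the median of the background probes, so that the sizes of their differences carry little meaning. HSPB1, a small heat shock protein gene, was 1.15 higher. Of the 10 highest genes 5 and of the 10 lowest 4 reached the 70th percentile of brightness, and at that minimum 30 genes were higher and 17 lower. Of 58 genes that differed at least 2-fold and had a second probe set, 40 differed the same way on it and 20 by at least 1.5-fold. The remaining lists in REC-1, which did not stand apart, had medians of 0.06 (cereblon, Ikaros and IRF4 axis), -0.07 (BCL2 family), -0.09 (p53 targets), 0.03 (MCL genes), -0.20 (NOTCH targets), -0.06 (MHC class II), -0.17 (cholesterol biosynthesis), -0.07 (oxidative phosphorylation) and -0.12 (heat shock). Heat shock genes did stand lower with the mean of probe sets (-0.19) and the probe set of median difference (-0.20), cholesterol genes with quantile normalization (-0.14), and the cereblon list stood higher with cyclic loess (0.12). Only 5 of 25 marker genes of T, NK, myeloid and erythroid cells were measured, and their median of 0.24 lay within the random range.

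**Figure D1:**
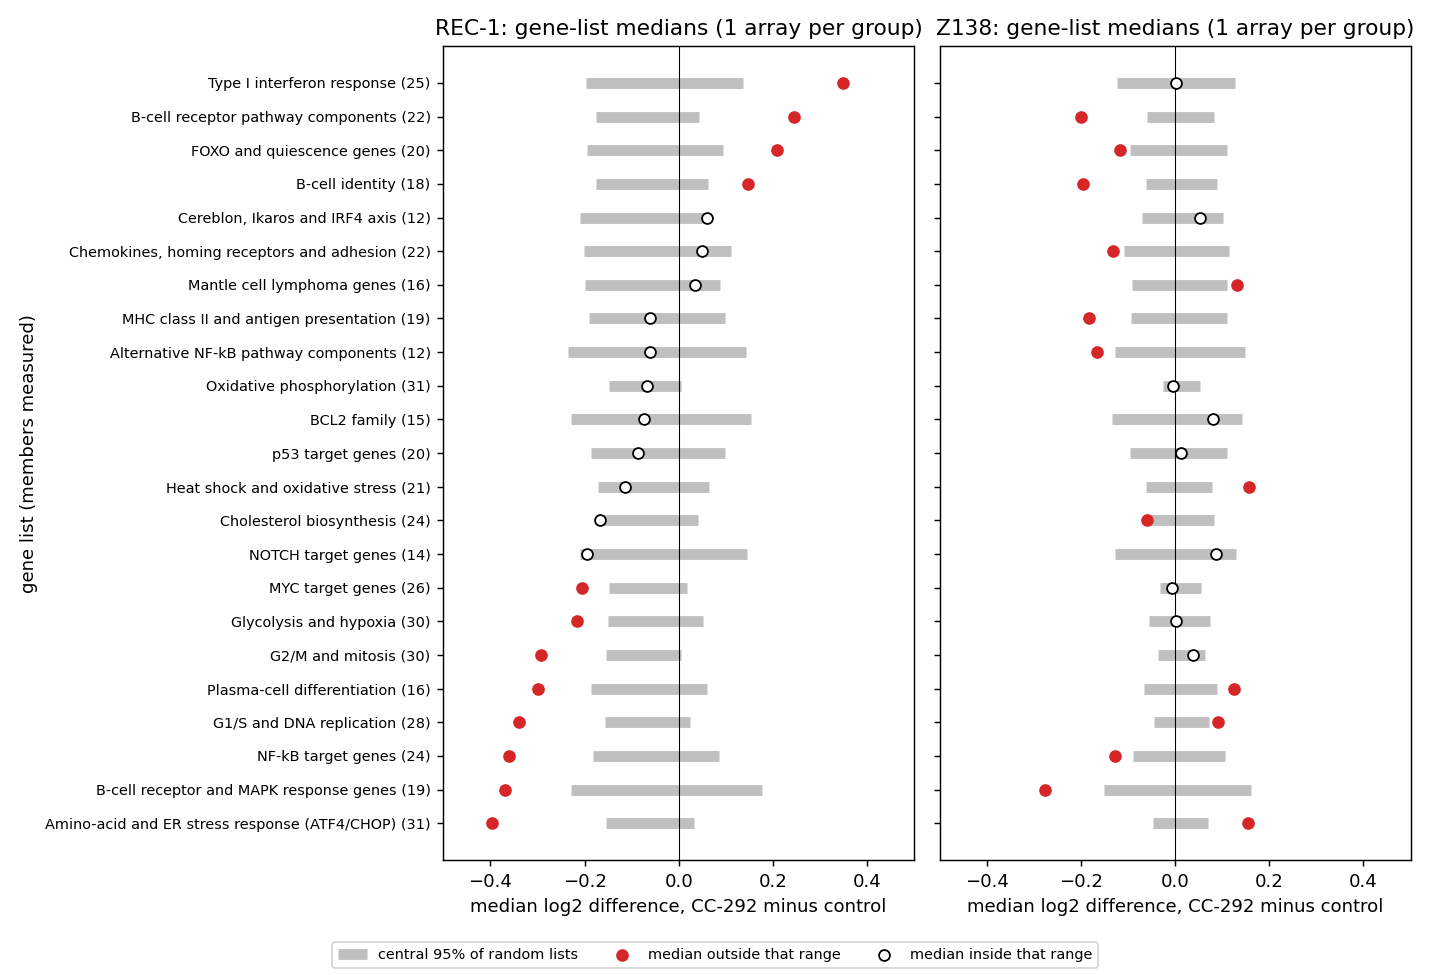
Median log2 difference (CC-292 minus control) of 23 gene lists in REC-1 (left) and Z138 (right), 1 array per group, with the number of members measured beside each name; the list of other blood cell types, with 5 members, is not drawn. Grey bars span the central 95% of 10000 random lists of like brightness and filled points lie outside them, such as the ATF4/CHOP list at -0.40 in REC-1 and 0.15 in Z138.

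The second comparison asked the same of Z138. In Z138, genes that mark B cells and components of the B-cell receptor pathway were lower as sets on the CC-292 array. The surface antigen gene CD52 was 2.65-fold lower and the receptor inhibitor gene CD22 2.12-fold lower. CCL3 was 2.15-fold lower, but lay below the brightness minimum on the CC-292 array, and CD69, an early activation antigen gene, was at -0.90. MHC class II and antigen presentation genes were lower in 18 of 19 cases. ATF4-response, plasma-cell and heat shock genes were slightly higher as sets. Fewer genes reached a 2-fold difference than in REC-1, 23 higher and 38 lower (0.564% of 10823). Here too, a gene could be counted that reached the brightness minimum only in REC-1.

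BTK differed by -0.11 (SD 0.01 over 2 probe sets), CCND1 by 0.12 (SD 0.11 over 4 probe sets), MYC by 0.06 and IRF4 by 0.07 (SD 0.04 over 2 probe sets). IKZF1, IKZF3 and CRBN differed by 0.16, -0.13 and 0.12 (SD 0.13, 0.11 and 0.06 over 3, 2 and 3 probe sets). In the NF-kB pathways, NFKB2 was at -0.47, MAP3K14 at -0.37, NFKBIA at -0.15 (SD 0.07 over 3 probe sets) and TRAF3 at -0.08 (SD 0.05 over 3 probe sets).

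B-cell receptor pathway components had a median of -0.20 in Z138, below all random lists, with 18 of 22 below 0. CD22 was at -1.08 (SD 0.52 over 2 probe sets), the phosphatase gene PTPN6 at -0.99 (SD 0.19 over 3 probe sets), PRKCB at -0.48 (mean -0.24 over 3 probe sets) and VAV1 at -0.45 (SD 0.29 over 2 probe sets), whereas BANK1 was at 0.82 (mean 0.23 over 3 probe sets). Differences were small for CD79A (-0.08) and SYK (0.09). B-cell identity genes also had a median of -0.20, with 15 of 18 below 0, among them CD52 at -1.40 (SD 0.07 over 2 probe sets), CD37 at -0.93 (SD 0.41 over 4 probe sets), the transcription factor gene SPIB at -0.90 and the kinase gene BLK at -0.76 (SD 0.17 over 2 probe sets). MHC class II genes had a median of -0.18, including HLA-DMB at -0.34 (SD 0.41 over 5 probe sets), with the costimulatory ligand genes CD86 at -0.91 (SD 0.65 over 4 probe sets) and CD80 at -0.63 (mean -0.29 over 5 probe sets).

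Of B-cell receptor and MAPK response genes, 15 of 19 were below 0 in Z138, with a median of -0.28. CCL3 was at -1.10, the immediate-early genes FOSB at -0.96 and NR4A1 at -0.68 (mean -0.31 over 6 probe sets), and CD69 at -0.90. This median was -0.09 with the mean of probe sets, inside the random range. NF-kB target genes (median -0.13, 18 of 24 below 0) and alternative NF-kB pathway components (median -0.17, 10 of 12 below 0) stood lower, with CD40 at -0.75 (SD 0.23 over 2 probe sets) in both lists and LTA at -0.52. Chemokine, homing receptor and adhesion genes had a median of -0.13, among them the homing receptor gene CXCR5 at -0.91 (SD 0.13 over 2 probe sets), ITGB7 at -0.87 and CCL5 at -1.01 (SD 0.80 over 2 probe sets). That call was lost without a brightness filter (-0.10) and with either other choice of probe set (-0.07). FOXO and quiescence genes stood lower at -0.12, with FOXO1 at -0.47 (SD 0.12 over 3 probe sets) and TXNIP at -0.18 (mean -0.05 over 5 probe sets), a call lost at the 70th percentile of brightness (-0.09) and with the other probe-set choices (-0.05 and -0.06). GABARAPL1 of that list was higher, at 0.66. Cholesterol genes stood lower at -0.06, a call lost without a brightness filter.

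On the higher side, ATF4 and CHOP response genes had a median of 0.15, with 25 of 31 above 0, for example CTH at 0.83, the cystine transporter gene SLC7A11 at 0.67 (SD 0.28 over 3 probe sets) and TRIB3 at 0.17 (mean 0.07 over 2 probe sets). Heat shock and oxidative stress genes had a median of 0.16 (18 of 21 above 0), with HSPA1B at 0.80, and 0.08 with the mean of probe sets, where the call was lost. Plasma-cell genes had a median of 0.12 with 14 of 16 above 0, among them PRDM1, the master regulator gene of plasma cells, at 0.70 (SD 0.29 over 4 probe sets) and XBP1 at 0.28. G1/S genes had a median of 0.09 with 16 of 28 above 0, including CCNE2 at 0.39 (SD 0.11 over 2 probe sets) and CDC6 at 0.28 (SD 0.18 over 2 probe sets), a call lost with the mean of probe sets (0.06). MCL genes had a median of 0.13, with SOX11 at 0.42 (mean 0.20 over 4 probe sets). This call was lost without a brightness filter (0.03) and with the other probe-set choices (0.01 and 0.05).

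The 10 lowest genes in Z138 were CCDC102B, STK39 (-1.45, mean -0.59 over 3 probe sets), CLMP, CD52, SMIM14 (-1.36, SD 0.15 over 2 probe sets), HSH2D, SLC22A23, SERPINA11, RHEX and CACNA1A. The 10 highest were GOLGA6L7 (1.53), COL6A1 (1.52, SD 1.60 over 2 probe sets), LOXL1, PRSS23, LINC01119, HBQ1, H2AC16, NDRG1 (1.27), WDPCP and NLRP7. HBQ1 lay below the background median on the control array. Only 1 of these 10 highest genes and 4 of the 10 lowest reached the 70th percentile of brightness, where 3 genes were higher and 16 lower. Of 26 genes with a second probe set, 20 differed the same way on it and 10 by at least 1.5-fold. Lists that did not stand apart in Z138 had medians of 0.05 (cereblon, Ikaros and IRF4 axis), -0.01 (MYC targets), 0.04 (G2/M), 0.08 (BCL2 family), 0.01 (p53 targets), 0.09 (NOTCH targets), 0.00 (interferon response), 0.00 (glycolysis and hypoxia), -0.01 (oxidative phosphorylation) and -0.10 (other blood cell types). Of these, glycolysis genes stood lower at the 70th percentile of brightness (-0.06), and other blood cell types stood higher with the mean of probe sets (0.27). The interferon response stood lower on second-brightest probe sets (-0.19, 11 members). On the brightest, 4 of its 25 members were at least 1.5-fold lower and 0 higher, while 13 were above 0.

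**Figure D2:**
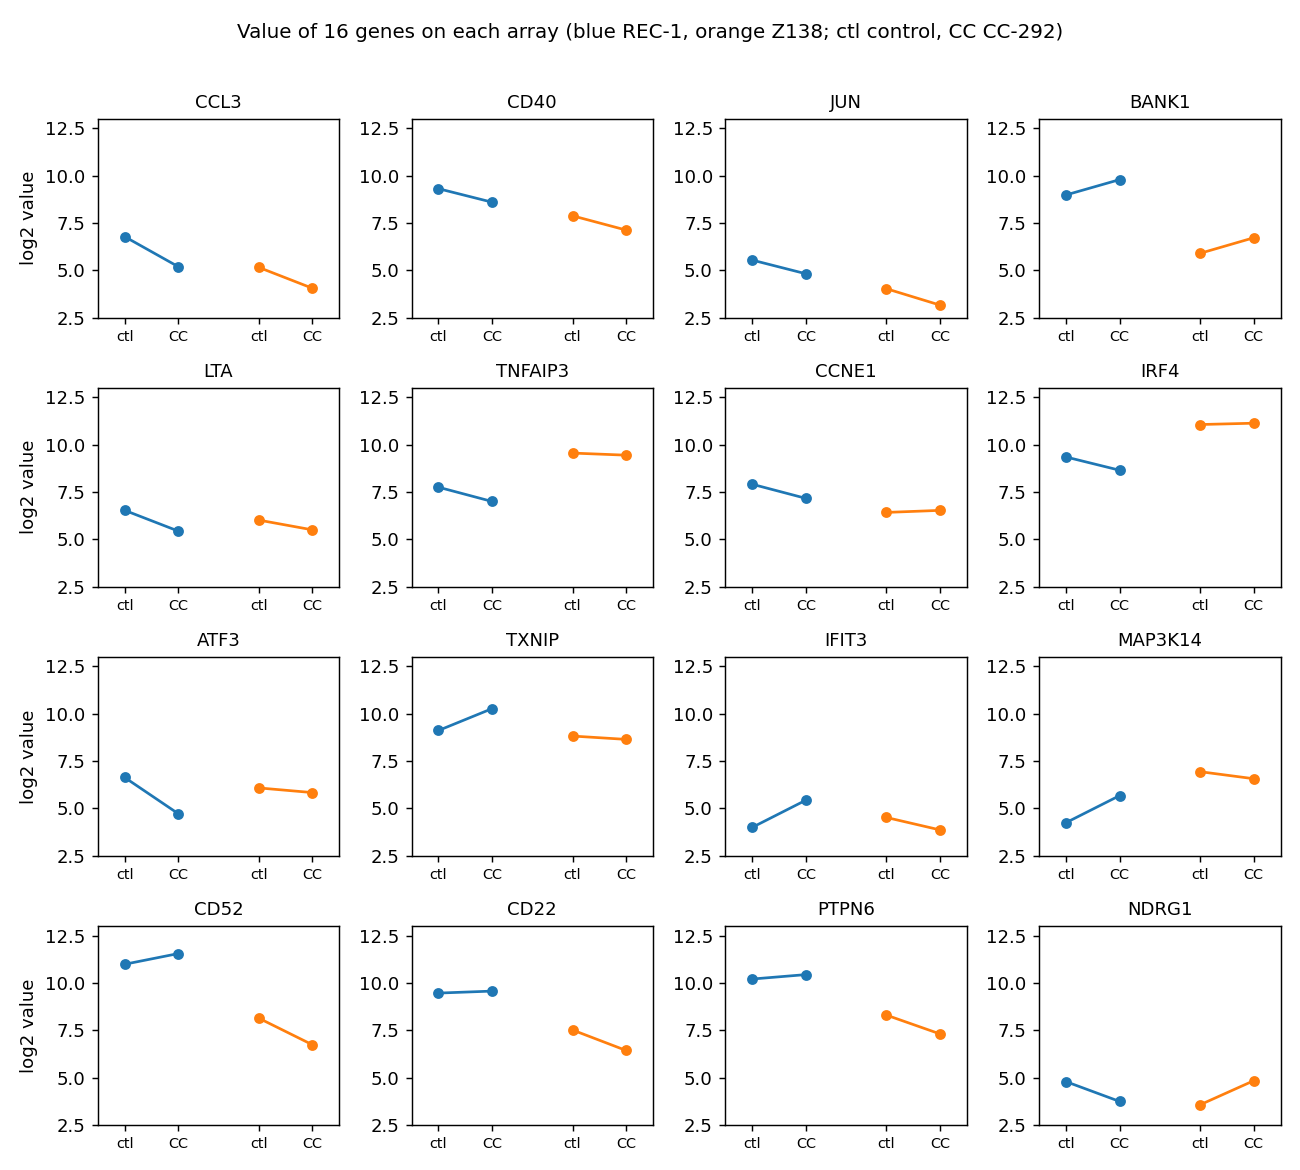
Log2 value of 16 genes on each of the 4 arrays, with a line joining the control (ctl) and CC-292 (CC) arrays of REC-1 (blue) and of Z138 (orange); each point is 1 array and there is no error bar. CCL3 was at 6.77 and 5.19 on the REC-1 arrays and at 5.15 and 4.05 on the Z138 arrays, and CD52 at 10.98, 11.55, 8.14 and 6.73.

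The third comparison asked which genes differed alike in both lines. On their brightest probe sets, CCL3, CCDC80, NHSL1, the AP-1 gene JUN and CD40 were lowest in both, and MGAT4A, SEC61A2, GAPT, BANK1 and the receptor tyrosine kinase gene MET highest in both. CCL3, the gene of a chemokine secreted by activated B cells, differed at least 2-fold in both lines (-1.59 and -1.10), the 1 gene lower in both at that size where independent sets would share 0.288. On the Z138 CC-292 array, however, CCL3 lay below the brightness minimum. CD40 was at -0.71 and -0.75 (SD 0.29 and 0.23 over 2 probe sets), JUN at -0.72 and -0.87 (SD 0.25 and 0.57 over 3 probe sets) and PECAM1, an adhesion receptor gene, at 0.72 and 0.66 (SD 0.09 and 0.14 over 2 probe sets). MGAT4A was at 1.13 and 0.93 (SD 0.72 and 0.46 over 3 probe sets), BANK1 at 0.81 and 0.82 (SD 0.16 and 0.52 over 3 probe sets) and SEC61A2 at 0.85 in both (SD 0.67 and 0.61 over 3 probe sets). In Z138 the second probe sets of BANK1, MET, GAPT, SEC61A2 and JUN differed the other way, at -0.15, -0.65, -0.38, -0.06 and 0.23, as did that of SEC61A2 in REC-1 (-0.26). GAPT on the Z138 control array (2.96) and CCDC80 on the REC-1 CC-292 array (2.85) lay below the background median. Of the gene lists, B-cell receptor and MAPK response genes and NF-kB target genes stood lower in both lines, the former a call lost in both with the mean of probe sets (-0.12 in REC-1 and -0.09 in Z138). That mean also takes probe sets below the brightness minimum. Only 4 members of the former list had a second probe set that reached it. On these the list stood lower in REC-1 (-0.64) but not in Z138 (-0.15).

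With the lines as the only replication (limma with cell line as a block, 1 residual degree of freedom), no gene passed a Benjamini-Hochberg adjusted p of 0.05. At an unadjusted p under 0.05 the same fit had 472 genes, 208 higher and 264 lower, against 541 that chance would give among 10823. The mean difference was -1.35 for CCL3 (SE 0.19), 1.03 for MGAT4A (SE 0.16), -0.79 for JUN (SE 0.16) and -0.73 for CD40 (SE 0.16), with a limma adjusted p of 0.9999 as the smallest of all genes. These SEs are moderated towards a prior from all genes, so they are not the spread of each gene between the lines alone. Across the 10823 genes the responses of the lines showed no clear correlation, with Pearson r = -0.0390 and Spearman rho = -0.0507 (genes are not independent replicates). Even within a line, the differences on the 2 brightest probe sets of 6761 genes correlated at only r = 0.252 in REC-1 and 0.242 in Z138. Noise of single probe sets thus limits the r, and the share of like signs, that a shared response could give. Of the 173 genes at least 2-fold different in REC-1, 86 had the same sign in Z138, and of the 61 in Z138, 27 had the same sign in REC-1.

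**Figure D3:**
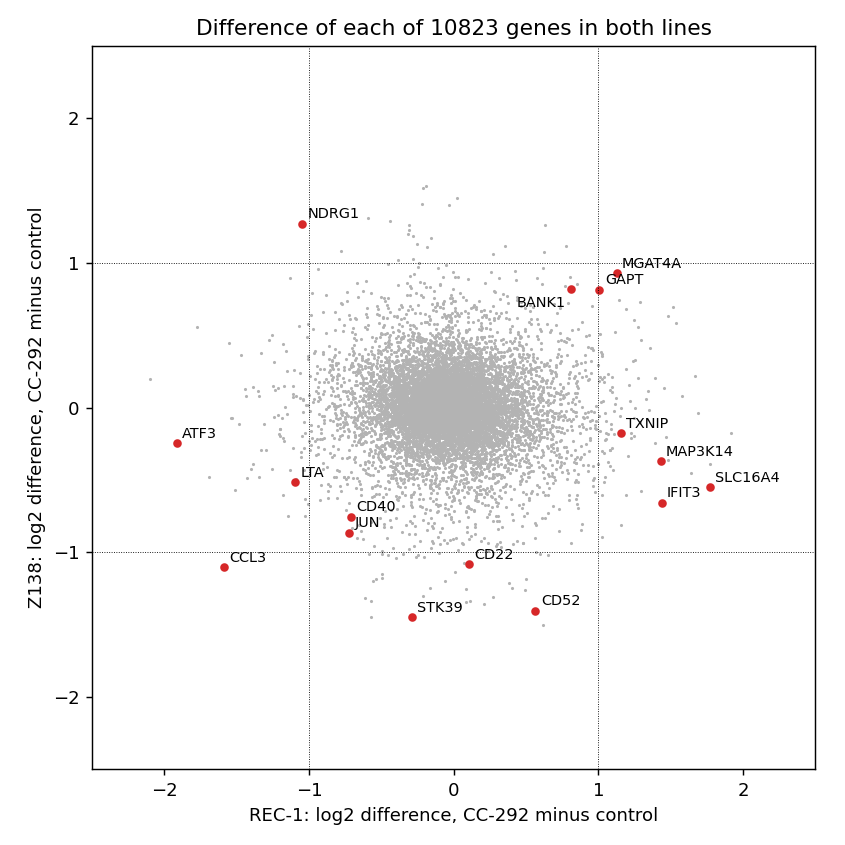
Log2 difference (CC-292 minus control) of each of 10823 genes in REC-1 (horizontal) against Z138 (vertical), 1 array per group, with 2-fold differences as dotted lines. The cloud shows no common direction (Pearson r = -0.0390), and CCL3 is the gene beyond 2-fold lower in both lines.

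The fourth comparison asked where the lines responded differently, as the REC-1 difference minus the Z138 difference. B-cell receptor pathway components and B-cell identity genes were higher in REC-1 relative to Z138, with CD52 at 1.97 (SD 0.18 over 2 probe sets), CD37 at 1.42 (SD 0.34 over 4 probe sets) and PTPN6 at 1.23 (SD 0.15 over 3 probe sets). ATF4-response genes were lower in 30 of 31 cases, with ATF3 at -1.67 and TRIB3 at -1.11 (SD 0.18 over 2 probe sets). Between the lines, 224 genes differed at least 2-fold in one direction and 221 in the other. These were 98 and 68 at the 70th percentile of brightness, and 106 and 79 with the mean of probe sets. None of these differences could be tested, since the interaction has no residual degree of freedom with 1 array per line and agent.

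Lists higher in REC-1 relative to Z138 were B-cell receptor components (median 0.44, 19 of 22 above 0), B-cell identity (0.34), FOXO and quiescence genes (0.31, with TXNIP at 1.33, SD 0.24 over 5 probe sets), the interferon response (0.31, with IFIT3 at 2.09 and TRIM22 at 1.46, SD 0.29 over 6 probe sets), chemokine and homing genes (0.16) and MHC class II genes (0.15). In the FOXO list 16 of 20 genes were above 0, but GABARAPL1 was at -1.56. Lists lower were the ATF4 response (-0.56), plasma-cell genes (-0.45, with PRDM1 at -1.05, SD 0.54 over 4 probe sets), G1/S genes (-0.34, 27 of 28 below 0), heat shock genes (-0.33), NOTCH targets (-0.33), G2/M genes (-0.32), MYC targets (-0.22) and glycolysis and hypoxia genes (-0.19). The remaining 10 lists had medians from -0.19 to 0.13 and did not stand apart. The highest single genes were SLC16A4 (2.32, SD 0.50 over 4 probe sets), LOXHD1, CCDC102B, RGPD4 and IFIT3, and the lowest were SHB, NDRG1, ERICH3, SNORD15B and NLRP11. SHB lay below the background median on 2 arrays, and NDRG1 was dim, with a difference in REC-1 of -1.05 that was 0.0506 with the probe set of median difference. MAP3K14 was at 1.80, NFKB2 at 0.79, IRF4 at -0.77 (SD 0.16 over 2 probe sets) and BTK at 0.29 (SD 0.09 over 2 probe sets). The calls for NOTCH targets (-0.16 to -0.24), glycolysis (-0.11 with cyclic loess), interferon (0.09 without a filter), MHC class II (0.09 with the mean of probe sets) and chemokines (0.16 with quantile normalization) were lost under such settings. On second-brightest probe sets the calls for G2/M (-0.14), NOTCH (-0.13) and glycolysis genes (-0.15) were lost.

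The last comparison set the 2 control arrays against each other, for the starting difference between the lines. Classical MHC class II genes were much lower in REC-1, with HLA-DPA1 at 4.63 against 13.49 in Z138 (SD of the difference 1.05 over 4 probe sets) and HLA-DRB1 at 3.18, close to the background median of 3.07, against 10.87. Plasma-cell genes were also lower in REC-1, among them the syndecan gene SDC1 and TNFRSF17. B-cell identity, B-cell receptor and NOTCH target genes were higher in REC-1, such as the complement receptor gene CR2, the homing receptor gene CXCR5 and the NOTCH effector gene HES4. At least 2-fold differences covered 24.3% of the genes, 1291 higher and 1341 lower in REC-1. Of 1661 such genes with a second probe set, 1597 differed the same way on it.

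MHC class II and antigen presentation genes had a median of -2.62, with 14 of 19 at least 2-fold lower in REC-1. HLA-DPB1 was at -6.71 (SD 2.07 over 11 probe sets), the class II transactivator gene CIITA at -2.59 (SD 0.95 over 3 probe sets) and the invariant chain gene CD74 at -1.73 (SD 0.08 over 5 probe sets). HLA-DRA was at -9.54, although its 3 probe sets disagreed (SD 4.42), and HLA-DOB differed by only -0.67. Plasma-cell genes had a median of -1.16 with 14 of 16 lower, including TNFRSF17 at -5.64, SDC1 at -4.88 (SD 1.62 over 3 probe sets), JCHAIN at -4.24 (SD 0.19 over 2 probe sets), PRDM1 at -1.76 (SD 0.90 over 4 probe sets, the second at 0.28) and IRF4 at -1.71 (SD 0.27 over 2 probe sets). The ATF4 response (median -0.62), p53 targets (-0.60), FOXO genes (-0.48) and G1/S genes (-0.34) also stood lower in REC-1, a call lost for p53 targets on second-brightest probe sets (-0.33). Among p53 targets the p21 gene CDKN1A was at -4.69 (SD 0.10 over 2 probe sets). However, 6 of 20 p53 targets were above 0, with GADD45A at 4.90 and RRM2B at 1.55.

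NOTCH target genes had a median of 2.17, with 9 of 14 at least 2-fold higher in REC-1, among them HES4 at 6.59 (below the background median in Z138), CR2 at 6.27 (SD 0.73 over 2 probe sets), HEY1 at 4.80 (SD 1.36 over 2 probe sets), HES1 at 3.65 (SD 1.44 over 4 probe sets) and FYN at 3.43. B-cell identity genes had a median of 1.66 with 12 of 18 at least 2-fold higher, for example CD37 at 4.23 (SD 1.91 over 4 probe sets), CD52 at 2.85 (SD 0.04 over 2 probe sets) and BLK at 1.49 (SD 0.01 over 2 probe sets), while BACH2 was at -2.26 (SD 0.62 over 2 probe sets). B-cell receptor components had a median of 1.01 with 20 of 22 above 0, led by CR2, PRKCB at 4.72 (SD 0.89 over 3 probe sets) and BANK1 at 3.08 (SD 0.41 over 3 probe sets). Interferon-response genes had a median of 0.40, which was -0.43 and inside the random range at the 70th percentile of brightness. The remaining 14 lists had medians from -0.21 to 0.23 and did not stand apart, although B-cell receptor and MAPK response genes, at -0.21, were at 0.95 and stood higher at the 70th percentile of brightness.

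BTK differed by 0.07 between the control arrays (SD 0.02 over 2 probe sets), CRBN by 0.03 (SD 0.25 over 3), IKZF3 by 0.08 (SD 0.24 over 2), TRAF3 by -0.13 (SD 0.17 over 3) and IKZF1 by -0.18 (SD 0.35 over 3). NFKB2 was lower in REC-1 at -2.70, MAP3K14 at -2.69, NFKBIA at -1.27 (SD 0.16 over 3 probe sets) and MYC at -0.93, whereas CCL3 was higher at 1.62. The 10 highest genes in REC-1 were CHI3L2 (8.39, SD 0.13 over 2 probe sets), GTSF1 (8.23), FCRL2 (7.99, SD 1.5 over 11 probe sets), BBOX1, AIM2, IGLL5, FCRL3, CD300A, UCHL1 and BHLHE41. The 10 lowest were HLA-DRA, HLA-DPA1 (-8.86), IGL (-8.11, but 0.22 with the probe set of median difference), GSTP1 (-7.89, SD 5.02 over 2 probe sets), HLA-DRB1, HLA-DPB1, UNC13C, HSPB1 (-6.27), LMCD1 and GCSAM. All 20 reached the 70th percentile of brightness.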

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

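The test of MAP3K14 and the check with an artificial brightness trend were chosen only after results were seen, as was the rule that a list needs 10 second probe sets, and the other tests before. Several lists stood apart in opposite directions in the 2 lines, and with 1 array per line and agent no difference between lines was tested. B-cell receptor pathway components had a median log2 difference of 0.24 in REC-1 and -0.20 in Z138, and B-cell identity genes 0.15 and -0.20. FOXO and quiescence genes were at 0.21 and -0.12, G1/S genes at -0.34 and 0.09, plasma-cell genes at -0.30 and 0.12, and ATF4-response genes at -0.40 and 0.15. Of these, FOXO genes in Z138 lost their call in 3 settings (-0.05 with the mean of probe sets), G1/S genes in Z138 with the mean of probe sets (0.06), and plasma-cell genes in REC-1 with both other probe-set choices (-0.15 and -0.10). NDRG1 differed at least 2-fold in opposite directions, by -1.05 in REC-1 and 1.27 in Z138, on 1 dim probe set, while the mean of all its probe sets gave -0.07 and 0.17. Among 2030 bright probe sets with no gene symbol or several, which the gene results leave out, 37 differed at least 2-fold between the REC-1 arrays and 10 between the Z138 arrays.

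In REC-1, 8 lists stood lower and 4 higher than random lists. After cyclic loess 12 of 12 stayed outside the random range on the same side, but the random lists were already matched on brightness, so this decides nothing about an intensity-dependent difference. On the second-brightest probe sets 10 of 12 stood apart, or 9 where at least 10 members had one. The latter share fell short of the mark set beforehand for the called lists as a group, so noise of single probe sets remains open in REC-1. The calls without support there were B-cell identity (0.08), plasma-cell genes (-0.16), and B-cell receptor and MAPK response genes, of which 4 had a second probe set. A difference between the cultures not caused by CC-292 cannot be told apart from an effect of CC-292, because the line has 1 control array. The ACTB 3' to 5' difference, which moved by -0.24 in REC-1 and -0.01 in Z138, also differed between these cultures.

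In Z138, 9 lists stood lower and 5 higher. After cyclic loess 14 of 14 stayed outside the random range on the same side, which decides nothing here either. On the second-brightest probe sets 8 of 14 stood apart and 13 lay on the same side. This share did not decide the test, which was set for the called lists as a group, so noise of single probe sets remains open in Z138. The other 6, which did not stand apart there, were B-cell receptor and MAPK response, alternative NF-kB, plasma-cell, MCL, chemokine and cholesterol genes. The difference between cultures cannot be told apart from CC-292 here either, with 1 control array. An effect of CC-292 was therefore not established in either line.

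MAP3K14 was 1.43 higher on the REC-1 CC-292 array and stood at -0.37 in Z138. Noise of a dim probe set was tested against 540 genes of like brightness, of which 2 (0.37%) differed by as much between the REC-1 arrays. The other MAP3K14 probe set, at -0.23 in REC-1, stayed below the brightness minimum, so that noise remains open.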

How the results depend on the processing

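No paired analysis was possible within a line because each group is 1 array and the labels carry no replicate numbers; across lines, the limma fit with the line as a block is itself paired. With 1 array per group no replicate could be left out, and leaving out a line leaves limma no residual degree of freedom. Agreement of a second probe set was the alternative chosen after the data were seen, as was the artificial brightness trend below. Of results that answer a comparison, 103 values were counted as kept and 48 as moved. A count was kept if it stayed within 1.5 times. The correlation of responses without a brightness filter, -0.0122 against -0.0390, was also counted as kept. Counts below are higher and lower by at least 2-fold.

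At the 70th percentile of brightness, which tests fewer genes, REC-1 had 30 and 17, Z138 3 and 16, and the difference between lines 98 and 68, and the correlation of responses was -0.0904. Without a brightness filter, which tests more genes, REC-1 had 135 lower, Z138 40 and 59, and the difference between lines 439 lower. With the mean of probe sets, REC-1 had 39 and 31, Z138 10 and 12, the difference between lines 106 and 79, and lists standing higher in Z138 numbered 3. With the probe set of median difference, these were 40 and 33, 11 and 14, and 110 and 88. Both settings also took probe sets below the brightness minimum, and the cause of the lower counts was not tested. At 1.5-fold, REC-1 had 468 and 512, Z138 236 and 273, the difference between lines 835 and 953, and the controls 2402 and 2348. At 3-fold, these were 6 and 5, 0 and 0, 26 and 22, and 620 and 628. With a second probe set in agreement, which only genes with more than 1 probe set can pass, they were 17 and 3, 1 and 9, 51 and 28, and 696 and 708.

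Centring, quantile normalization and cyclic loess kept these counts within 1.5 times. In limma, 0 genes passed an adjusted p of 0.05 in the 9 settings run. The smallest adjusted p ranged from 0.0927 with an intensity trend to 1 without the block, and 13 to 881 genes had an unadjusted p under 0.05. Of list medians, 630 kept their call, 30 lost it, 7 gained one and 1 changed sign. The last was the interferon response between controls, -0.43 at the 70th percentile of brightness, which lay inside the random range. Of named genes, 1893 values moved by less than the spread between probe sets, 211 moved by more and 2 reversed. The brightness settings cannot change the value of a gene, so their 311 (no filter) and 240 (70th percentile) values were kept by design. Those that moved came mainly from the choice of probe set. With the mean of probe sets 104 moved and 207 were kept, and with the probe set of median difference 97 moved and 212 were kept. With the probe set of median difference, NDRG1 in REC-1 was at 0.0506 and IGL between controls at 0.22, whose probe sets disagree.

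An artificial trend of 1 log2 from the dimmest to the brightest genes was added to see whether cyclic loess can decide about list calls. It kept 11 (rising) and 11 (falling) of 12 calls in REC-1 and 9 and 8 of 14 in Z138. Among lists without a call it made 0 and 3 of 12 in REC-1 and 0 and 1 of 10 in Z138. The calls made were counted after the calls kept were seen, and these measures differed by line, so an intensity-dependent difference was left open in both.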

Other observations

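The gene families of this part were picked after the data were seen, so that their place among random lists is no independent evidence. Proteasome subunit genes were lower in REC-1 in 37 of 42 cases, with a median log2 difference of -0.17, while 29 of 42 were above 0 in Z138 (median 0.06). PSME3 was the lowest at -0.59, and the immunoproteasome gene PSMB8 was the highest at 0.37, with -0.33 in Z138. Aminoacyl-tRNA synthetase genes were lower in REC-1 in 14 of 17 cases (median -0.20), among them MARS1 at -0.50. Ribosomal protein genes had a median of 0.05 in REC-1, with 50 of 71 above 0. Genes of protein entry into the ER and glycosylation there (signal peptidase, signal recognition particle, translocon-associated, oligosaccharyltransferase and ribophorin subunits) were above 0 in Z138 in 15 of 17 cases (median 0.14), with SPCS2 at 1.11 in Z138 and 0.78 in REC-1 and SSR3 at 0.33 in Z138 and -0.68 in REC-1. Of 3 metallothionein genes, MT1X was at 0.95 in REC-1 and MT2A at -0.01, while MT1E was higher but lay below the background median on the control array.

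Between the control arrays, HLA class I genes were lower in REC-1 in 5 of 5 cases and at least 2-fold in 4, with a median of -4.25 and HLA-F at -4.87. Toll-like receptor genes were at least 2-fold higher in 7 of 8 cases (median 2.07), among them TLR4 at 3.51 and TLR10 at 3.26, with TLR7 at -0.70. Fc receptor-like genes were at least 2-fold higher in 4 of 8 cases (median 1.87) and below 0 in 2, FCRLA at -0.68 and FCRL6 at -0.27, with FCRL1 at 6.09, FCRL2 at 7.99 and FCRL3 at 7.23. Of 7 immunoglobulin genes, IGKC was at 5.76 and IGLL1 at -4.94.

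CCND1 showed the same level in both lines on its brightest probe set, 11.87 in the REC-1 control and 11.83 in the Z138 control. The other 3 probe sets read 5.07 against 9.40, 4.62 against 7.17 and 3.41 against 7.07, lower in REC-1 by log2 differences of -4.33, -2.55 and -3.66. The SD over the 4 probe sets was 1.92, and 34 (0.503%) of the other genes with at least 2 probe sets had one as large. Which parts of the transcript these probe sets read is not analysed here.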
